A study of Mus musculus with 14 samples.

How the data were processed

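RNA-seq was done on 14 libraries of mouse neural stem cells, made with the TruSeq kit from total RNA per the labels. Per the submitters' processing notes, reads were aligned with Bowtie and quantified with RSEM against mm10, and versions and aligner settings are not given in the sources used here. The deposited files give for each of 29713 genes an expected count, a TPM and an FPKM, per the file headers. The authors' expected counts are RSEM estimates and not whole for 10.4 to 13.1% of genes, and they were rounded to whole numbers here. Reads shared by related genes are divided among them by RSEM, so counts of ribosomal protein genes and of other families with pseudogenes depend on that step. A GENCODE annotation of the same build gave positions, GC content and symbols, and 29202 of the 29713 identifiers were found in it. Mitochondrially encoded genes are not analysed here.

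Each library is 1 condition. The spread was therefore taken from an additive model of stage and treatment over the 12 libraries of the drug experiment, with 6 residual degrees of freedom, so that it holds both library noise and any drug effect that differs between stages. The tests were edgeR's quasi-likelihood tests with TMM scaling and its filter on low counts, which kept 13144 genes (13855 over 14 libraries), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Stage comparisons, naloxone against NC, DAMGO against NC and naloxone against DAMGO came from this model, drug by differentiation state from a model with an interaction and 4 residual degrees of freedom, and the passage comparisons from a model of 14 libraries in which each reference library has a term of its own. These comparisons, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The test of drug effects within each stage, the removal of a trend on GC content and length, and the fits without the day 2 libraries were added after the data had been seen.

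The named genes follow a rule. For day 8, each drug and passage 13 it takes the 10 largest rises and 10 largest falls past the threshold with a mean of at least 5 CPM and the same direction in every matched pair, and for the other comparisons 5 each way. Where fewer than 5 pass in a direction, the 5 with the smallest p may be named as not past. Up to 4 members past the threshold with the largest fold are named per list, and 20 genes of opioid receptors and peptides, cell types, Tet enzymes and Tlr4 are always reported. Genes with predicted names are counted and not named.

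The 36 gene lists hold stem and progenitor, S phase, G2 and M phase, neuronal, astrocyte, oligodendrocyte precursor and mature oligodendrocyte genes, opioid system and opioid signalling genes, Notch, Wnt, BMP and Hedgehog genes, immediate early, interferon, inflammatory, DNA methylation, imprinted, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response, p53, senescence, matrix, ribosomal protein, growth factor, and synapse genes, markers of microglia, endothelium, mesenchyme and pericytes, neural crest and Schwann cells, ependyma and pluripotent cells, sex-linked genes, and mitochondrial mRNAs. Some genes stand in more than 1 list, such as Sox10, Hes5, Tnc and Vegfa. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the residuals.

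A fold against a group without counts is a lower bound computed with a floor of 3 counts over the group, and for 1 to 3 counts the ratio of CPM is given with a 95% counting interval. Other log2 changes are fitted values with their SE. The alternatives tried were scaling with the size factors of DESeq2, TPM with a pseudocount of 1 or 0.1, no filter on low counts, DESeq2, limma-voom, limma on log2 TPM, a minimum change of 2-fold, a trend on GC content and length fitted with mgcv within a stage or across libraries, the passage 8 reference added as an NC library, the differentiating libraries alone for the drugs, and each library left out. The treatment names were permuted within stages in 50 draws, and the 6 libraries of each pair of stages were split in every way. The code was tested on simulated data with known changes of 1.5, 2 and 4-fold. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3.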

Results

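RNA from cultured mouse neural stem cells (NSC) of the OG2 strain, which carries a Pou5f1 reporter, was sequenced in 14 libraries. Naloxone is an antagonist of opioid receptors and DAMGO is a peptide agonist selective for the mu opioid receptor. The series asks how these drugs act while NSC proliferate and while they differentiate. A set of 12 libraries at passage 8 crossed 4 stages (undifferentiated, and day 2, day 4 and day 8 of differentiation) with 3 treatments, naloxone, DAMGO and a control that the labels call NC. The other 2 libraries were NSC at passage 8 and passage 13 with no named treatment. Each condition had 1 library, so no condition was replicated. The libraries held 4143030 to 9070533 estimated counts, and 3 counts in a library equalled 0.354 to 0.693 CPM (counts relative to the library total scaled by TMM). Intervals and floors in what follows cover counting error only. For a stage, the mean and SD are over its 3 libraries, 1 per treatment. The first principal component held 66.2% of the variance of the 14 libraries, and the second held 14.7%.

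The comparison of day 8 with undifferentiated cells asks what differentiation changed. By day 8 genes of astrocytes had risen and genes of cell division had fallen. Gfap, the intermediate filament of astrocytes, stood at 8781 ± 322 CPM against 2.33 ± 1.67 in undifferentiated cells (SD, n = 3), a rise of 11.91 ± 0.29 on the log2 scale (SE). Clu, which encodes the secreted chaperone clusterin, went from 3.25 ± 1.20 to 3807 ± 259 CPM, the water channel gene Aqp4 from 2.76 ± 0.583 to 606 ± 199, and Apoe, which encodes a lipid carrier, from 93.1 ± 5.69 to 15488 ± 975. Of 21 measured astrocyte genes, 19 rose and 2 did not pass the test (20 rose when adjusted over the list alone), with a camera adjusted p = 0.00403 with an estimated correlation. All 25 measured genes of S phase and all 25 of G2 and M phase fell. The proliferation marker Mki67 fell from 1308 ± 42.6 to 1.10 ± 0.346 CPM and Ccne2, a cyclin of S phase entry, from 65.3 ± 3.99 to 1.09 ± 0.877. The adjusted p was 0.0161 for S phase and 0.00710 for G2 and M phase with an estimated correlation. The test called 10532 of 13144 genes, 5470 higher and 5062 lower, and 6241 of them changed at least 2-fold.

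Among the 10 genes with the largest rise at day 8, 6 had no count in any undifferentiated library, and their folds are lower bounds against a floor of 3 counts over the group. Bmp6, a ligand of the BMP family, reached 188 ± 27.7 CPM, at least 1055-fold higher. Fxyd1, a regulator of the sodium pump, was at least 639-fold higher, Lgi4, a secreted protein of glia, at least 613-fold, and Entpd2, which breaks down extracellular ATP, at least 610-fold. Eva1a was at least 223-fold higher and Angptl4, an inhibitor of lipoprotein lipase, at least 200-fold. S1pr3, a receptor for sphingosine 1-phosphate, reached 457 ± 17.3 CPM, a ratio of 3757 (95% counting interval 1040 to 31028). The complement gene C3 reached 256 ± 29.1 CPM, a ratio of 2141 (592 to 17682), and Cnmd 211 ± 19.7 CPM, a ratio of 3435 (616 to 135710). Among the 10 largest falls was Cenpe, a kinetochore motor, which went from 217 ± 5.61 to 0.102 ± 0.0948 CPM, and the undifferentiated level was 2119 times the day 8 level (586 to 17502). For the kinetochore gene Knl1 that ratio was 839 (287 to 4072), for Depdc1a 705 (195 to 5832) and for Parpbp 614 (110 to 24314). Ncapg, a condensin subunit, changed by -9.36 ± 0.38 on the log2 scale, Hmmr by -8.93 ± 0.46, and Aspm, a protein of the spindle pole, by -8.84 ± 0.55. The peroxidase gene Lpo went from 12.2 ± 1.48 CPM to no count in any day 8 library, at least 79.8-fold lower.

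Genes of the oligodendrocyte lineage moved apart at day 8. Of 11 measured precursor genes 5 rose and 6 fell. The receptor gene Gpr17 rose from 6.59 ± 1.44 to 482 ± 38.8 CPM, Sox10, a transcription factor of the lineage, from 2.13 ± 0.0760 to 36.7 ± 3.68, and Pdgfra, the receptor that marks precursors, from 24.6 ± 2.64 to 293 ± 20.5. Olig2, a factor of the same lineage, fell from 801 to 312 CPM and the proteoglycan gene Cspg4 from 187 ± 15.3 to 49.5 ± 6.37. The median log2 change of this list was -0.59, its mean was 0.70 and camera put it higher without a call (adjusted p = 0.524 with an estimated correlation). Of 14 measured genes of differentiated oligodendrocytes 10 rose and 1 fell (adjusted p = 0.231 with an estimated correlation). Mbp, which encodes a myelin protein, rose from 1.25 ± 0.574 to 56.8 ± 0.580 CPM. Of 21 neuronal genes 12 rose and 6 fell. Rbfox3, which encodes the neuronal nuclear antigen NeuN, rose from 1.08 ± 0.238 to 12.7 ± 1.59 CPM, and Elavl4, an RNA-binding protein of neurons, fell from 70.4 ± 0.580 to 4.82 ± 2.0. Of 21 stem and progenitor genes 11 rose and 10 fell. Nes, the intermediate filament of progenitors, fell from 1800 ± 77.8 to 268 ± 41.3 CPM and Tnc, a matrix glycoprotein, from 1644 ± 32.5 to 50.3 ± 8.27. Sox2, a transcription factor of neural stem cells, rose from 329 to 416 CPM.

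Signalling genes at day 8 were as follows, with counts adjusted over the list alone identical unless given. Of 11 BMP targets and antagonists 10 rose and none fell (adjusted p = 0.137 with an estimated correlation), among them Id4, an inhibitor of helix-loop-helix factors, from 1.74 ± 0.535 to 349 ± 17.8 CPM. Of 12 inflammatory and NF-kappaB genes 9 rose and 1 fell (0.137). Vcam1, an adhesion molecule, rose from 8.99 ± 2.36 to 357 ± 44.1 CPM, and Tlr4, the receptor for lipopolysaccharide, fell from 3.14 ± 1.23 to 0.261 ± 0.103. Of 15 interferon-stimulated genes 12 rose and 1 fell (0.201), with Gbp2 going from 0.559 ± 0.232 to 73.4 ± 8.73 CPM. Of 11 Wnt targets 3 rose and 8 fell (0.231), and Ccnd1, which encodes cyclin D1, fell from 2396 ± 29.4 to 37.4 ± 2.0 CPM. Of 22 immediate early genes 9 rose and 10 fell, with the transcription factor Egr1 going from 388 ± 26.1 to 5.97 ± 1.80 CPM. With TPM scaling in place of TMM the median turned its sign for the Notch list, with 7 of 15 higher and 7 lower, for the Hedgehog list, with 3 of 9 higher and 4 lower, and for the list of proteins downstream of opioid receptors, with 9 of 23 higher and 9 lower. Cdon, a Hedgehog co-receptor, fell from 177 ± 4.91 to 28.7 ± 2.88 CPM, and Gnao1, a G protein subunit, rose from 29.7 ± 3.18 to 175 ± 16.3. Among 11 growth factor genes 5 rose and 4 fell, and Cntf, a neurotrophic cytokine, rose from 4.35 ± 0.706 to 267 ± 38.9 CPM. Among 20 synapse and channel genes 6 rose and 9 fell, with the glutamate receptor gene Gria2 going from 790 ± 25.6 to 37.9 ± 16.7 CPM and Gria1 from 1.44 ± 0.848 to 23.9 ± 1.01.

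Genes of metabolism and growth arrest also moved by day 8. Of 23 cholesterol genes 16 fell and 1 rose (adjusted p = 0.633 with an estimated correlation), with Idi1, an isomerase of the pathway, going from 522 ± 5.66 to 85.3 ± 25.2 CPM. All 25 measured ribosomal protein genes fell (0.633), Rpl4 from 1390 ± 14.6 to 591 ± 86.9 CPM. The SDs of both genes at day 8 were wider than in undifferentiated cells. Of 24 nuclear genes of oxidative phosphorylation 17 rose and 1 fell, and of 23 genes of glycolysis and hypoxia 7 rose and 15 fell. Of 17 p53 and apoptosis genes 3 rose and 11 fell (0.156), and of 11 genes of cell cycle inhibitors and senescence 3 rose and 7 fell. Cdkn2b, a kinase inhibitor, rose from 7.17 ± 1.19 to 76.4 ± 5.81 CPM and Hmga2, a chromatin protein of growing cells, fell from 27.1 ± 0.883 to 0.181 ± 0.177. Of 22 genes of the unfolded protein response 8 rose and 9 fell. Of 18 genes of DNA methylation and its removal 7 rose and 6 fell, and the sign of the list median turned with TPM scaling. In that list Dnmt1, the maintenance methyltransferase, fell from 450 ± 24.3 to 86.2 ± 2.18 CPM and Gadd45g rose from 11.2 ± 1.37 to 92.9 ± 7.10. Of 16 imprinted genes 9 rose and 6 fell, with H19, a noncoding RNA, going from 1.43 ± 0.650 to 43.3 ± 4.72 CPM. Of 14 matrix genes 8 rose and 4 fell.

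**Figure D1:**
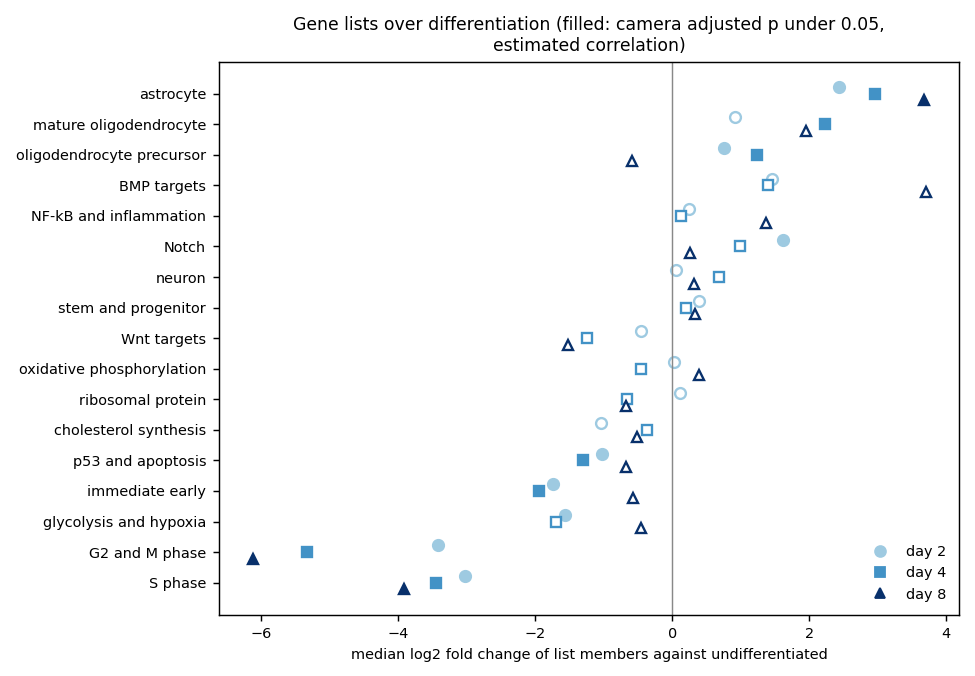
Median log2 fold change of the tested members of 17 gene lists at day 2, day 4 and day 8 against undifferentiated cells, with filled points where camera gave an adjusted p under 0.05 with an estimated correlation. Astrocyte genes are to the right and both cell cycle lists to the left at every day, and with genes at no count set to their bound the median that moved most among those plotted was mature oligodendrocyte at day 2, from 0.92 to 0.62.

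Days 2 and 4 show which of these changes came early. Cell cycle genes had fallen by day 2, with all 25 genes of S phase and all 25 of G2 and M phase lower at day 2 and at day 4, and the adjusted p with an estimated correlation was 0.00276 and 0.000743 at day 2. Mki67 was at 21.9 ± 11.4 CPM at day 2 and 9.36 ± 3.68 at day 4. Oligodendrocyte precursor genes were called higher at both days, with 7 of 11 higher at each (0.0193 and 0.0109). Gpr17 stood at 614 ± 55.5 CPM at day 2 and 1188 ± 22.9 at day 4, and Pdgfra at 324 ± 16.5 and 558 ± 20.9. Of the astrocyte genes 18 of 21 were higher at day 2 and 17 at day 4 (0.00276 and 0.00223), while Gfap was at 509 ± 45.4 CPM at day 4. Genes of differentiated oligodendrocytes passed at day 4, with 11 of 14 higher (0.0270), and not at day 2, with 6 higher (4 adjusted over the list alone, adjusted p = 0.321 with an estimated correlation). Dcx, which encodes a microtubule protein of young neurons, was at 12 CPM in undifferentiated cells, 48.9 at day 2, 335 ± 11.6 at day 4 and 80.3 at day 8. Tubb3, a tubulin of neurons, was at 17.3, 104, 108 and 106 CPM at these stages, and S100b at 1.90, 15.8, 19.8 and 50 CPM. The day 2 comparison called 9156 genes, 4436 higher and 4720 lower, of which 4431 changed at least 2-fold. Day 4 called 8192, 4122 higher and 4070 lower, of which 3728 changed at least 2-fold. Day 8 against day 2 called 7727, 4239 higher and 3488 lower, of which 3116 changed at least 2-fold.

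At day 2 the 5 largest rises were in Lipg, an endothelial lipase gene, with a ratio of 221 (60.9 to 1831), Abhd3, at 6.95 ± 0.21 on the log2 scale, Ccdc190, with a ratio of 133 (45.2 to 647), Gpr17, at 6.52 ± 0.14, and Ndrg2, which marks astrocytes, at 6.36 ± 0.12. The 5 largest falls were in Cenpe at -6.38 ± 0.28, Arc, an immediate early gene of synapses, at -6.38 ± 0.25, Knl1 at -6.19 ± 0.22, the kinesin gene Kif20b at -6.15 ± 0.26 and the integrin gene Itga4 at -6.08 ± 0.30. At day 4 the 5 largest rises were in genes with no count in undifferentiated cells, Gpr149 (at least 252-fold), Entpd2 (172), Enpp6, a gene of newly formed oligodendrocytes (125), Angptl4 (116) and Lgi4 (111). The largest falls at day 4 were in Cpne7, whose undifferentiated level was 489 times the day 4 level (87.4 to 19353), Mki67 at -7.14 ± 0.30, Knl1 at -6.81 ± 0.24, Cenpe at -6.81 ± 0.30 and Angpt2, a ligand of blood vessel growth, at -6.75 ± 0.33.

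Other lists passed at days 2 and 4. Immediate early genes were lower, 16 of 22 at day 2 and 19 at day 4 (adjusted p = 0.0229 and 0.0320 with an estimated correlation), and so were p53 genes, 13 of 17 at both days (0.0396 and 0.0381), and genes of cell cycle inhibitors and senescence, 8 of 11 and 7 of 11 (0.0396 and 0.0334). Plk2, a p53 target, was at 332 ± 20.4 CPM in undifferentiated cells and 17.0 ± 2.38 at day 4. Glycolysis and hypoxia genes were lower, 20 of 23 at both days, with an adjusted p = 0.0454 at day 2 and 0.0511 at day 4 with an estimated correlation. Ldha, which makes lactate, went from 973 ± 57.0 CPM to 136 at day 2, 89.9 ± 7.95 at day 4 and 333 at day 8. Notch genes passed at day 2, with 9 of 15 higher and 3 lower (0.0396), and not at day 4, with 8 higher and 3 lower (0.176). Hes5, a Notch target, was at 18.5 ± 3.70, 305 ± 46.7 and 179 ± 10.2 CPM in undifferentiated cells, at day 2 and at day 4. Cholesterol genes were lower, 18 of 23 at day 2 (19 adjusted over the list alone, 0.338) and 16 at day 4 (0.643). All 25 ribosomal protein genes were lower at day 4 (0.486), while at day 2 there were 6 higher and 2 lower (1 and 1 adjusted over the list alone). Of 24 oxidative phosphorylation genes 19 were lower at day 4 (0.643), in contrast to the 17 higher at day 8. With TPM scaling the median of all genes lay at 0.16 at day 4 and -0.16 at day 8 on the log2 scale, against 0.00 and 0.05 with TMM, and day 4 then called 4925 higher and 2967 lower while day 8 against day 2 called 2984 higher and 4167 lower.

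**Figure D2:**
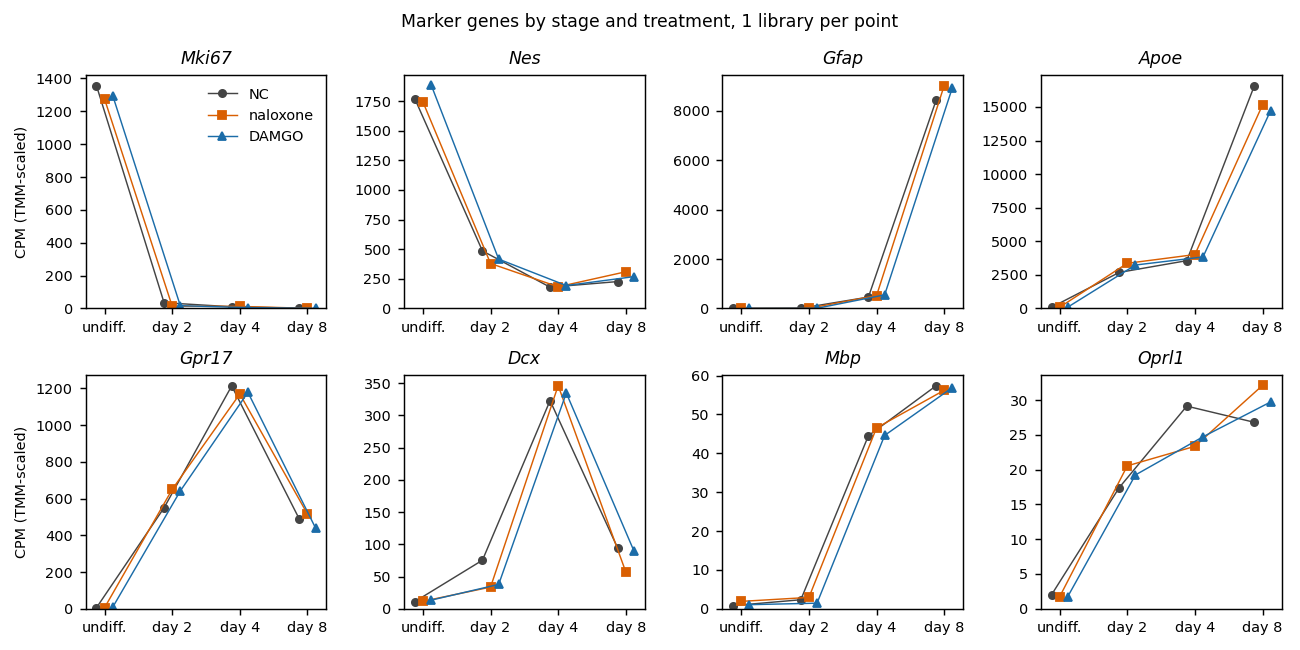
CPM of 8 genes in each of the 12 libraries, by stage on the x axis and by treatment, where each point is 1 library. Mki67 and Nes are highest in undifferentiated cells, Gfap and Apoe at day 8 (8781 and 15488 CPM), and Gpr17 and Dcx at day 4 (1188 and 335 CPM).

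RNA of the classical opioid receptors was not detectable at this depth or nearly so. Oprm1, the gene of the mu receptor to which DAMGO binds (chromosome 10, 6758506 to 7038198 of mm10), and Oprk1, that of the kappa receptor (chromosome 1, 5588466 to 5606131), had no count in any of the 14 libraries, which allows up to 0.0349 CPM over all of them. Oprd1, the gene of the delta receptor, had 2 counts in total and the enkephalin precursor gene Penk had 4. Pomc, which encodes the precursor of beta-endorphin, had 40. Oprl1, the nociceptin receptor gene (chromosome 2, 181715016 to 181720985), was measured in every library and rose from 1.83 ± 0.160 CPM to 19.1 ± 1.58 at day 2, 25.7 ± 3.02 at day 4 and 29.6 ± 2.66 at day 8. Naloxone has little affinity for that receptor. The dynorphin precursor gene Pdyn rose to 4.89 ± 0.491 CPM at day 8, a ratio of 39.9 (10.7 to 334). Ogfr, the gene of the opioid growth factor receptor, rose from 86.7 ± 2.07 CPM to 171 ± 13.5 at day 2, 115 ± 5.29 at day 4 and 126 ± 4.92 at day 8, and its day 8 change was -0.09 when the GC and length trend was removed across all libraries. Ogfrl1 fell from 16.0 ± 0.868 CPM to 4.95 ± 0.941 at day 8. Of the 4 genes measured in this list 3 were higher and 1 lower at day 8, and the same number at day 4, with 2 higher and 1 lower at day 2.

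The genes that respond to a drug in every stage are tested by naloxone against NC over the 4 stages, with 1 library of each per stage. No gene passed edgeR's threshold for naloxone (0 of 13144, smallest adjusted p = 0.469), with 1332 genes at an unadjusted p under 0.05 against 657 expected by chance. The naloxone libraries of day 2 and day 8 had a trend on GC content against NC (r across genes 0.611 and 0.617), which that count includes. The genes with the smallest p that were higher in 4 of 4 stages were Svop, a synaptic vesicle protein, at 19.6 ± 5.29 CPM against 14.2 ± 2.79 (SD, n = 4, log2 difference 0.45 ± 0.10), Ubtd1 at 14.4 ± 4.26 against 10.5 ± 3.59, Cby1, a protein of the ciliary base, at 50.6 ± 13.5 against 40.4 ± 12.1, Nudt1, which clears oxidised nucleotides, at 10.6 ± 3.07 against 7.41 ± 2.66, and Ccdc189 at 9.33 ± 6.38 against 6.64 ± 5.28. Those with the smallest p among genes lower in 4 of 4 stages were Zfp874b (-0.72 ± 0.18), Osbpl6 (-0.33 ± 0.08), Pigg (-0.41 ± 0.10), the axon guidance receptor gene Robo2 (-0.59 ± 0.15) and Zfp974 (-0.66 ± 0.17), and none of these 10 passed. DESeq2, limma-voom and limma on log2 TPM also called 0 for this and the next 2 comparisons. In data simulated for naloxone against NC, with the same change in all 4 stages, 55% of genes changed 1.5-fold, 93.8% of those changed 2-fold and 100% of those changed 4-fold were called. Here and in the simulations of changed genes below, the changed genes had a mean of at least 5 CPM. No trend between libraries was simulated with them. The shares called therefore do not cover genes of lower expression.

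For DAMGO against NC 0 genes passed in edgeR (314 at an unadjusted p under 0.05, fewer than the 657 expected by chance, smallest adjusted p = 0.951). Higher in 4 of 4 stages without passing were Inf2, a formin that shapes actin (0.48 ± 0.13), Pygl, a glycogen phosphorylase (0.92 ± 0.26), Pcdhgb7 (0.44 ± 0.12), the amino acid transporter gene Slc7a5 at 194 ± 69.1 CPM against 170 ± 58.1 (0.19 ± 0.05), and Gsto1 (0.31 ± 0.09). Lower in 4 of 4 stages without passing were Tnfrsf22 at 16.2 ± 5.94 CPM against 22.9 ± 6.24 (-0.53 ± 0.11), Nqo2 (-0.36 ± 0.10), Aspdh (-1.03 ± 0.29), Zfp974 (-0.56 ± 0.17) and Serpini1, an inhibitor of proteases in neurons (-0.54 ± 0.17). In data simulated for DAMGO against NC 61.3% of genes changed 1.5-fold, 88.8% of those changed 2-fold and 100% of those changed 4-fold were called. The direct comparison of naloxone with DAMGO called 0 genes in edgeR (229 at an unadjusted p under 0.05, also fewer than 657, smallest adjusted p = 0.9998). Igfbp3, which binds insulin-like growth factors, differed by 0.27 ± 0.07 on the log2 scale, Id1 by 0.34 ± 0.10, the sterol desaturase gene Sc5d by -0.30 ± 0.08 and Pts, of tetrahydrobiopterin synthesis, by -0.43 ± 0.11, none of them past the threshold. Without the DAMGO day 8 library the counts were 2 for DAMGO against NC and 2 for naloxone against DAMGO. In data simulated for naloxone against DAMGO 53.8% of genes changed 1.5-fold and 85% of those changed 2-fold were called.

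The log2 changes of the drugs against NC correlated across 8962 genes, which are not independent replicates (r = 0.879, rho = 0.783), and both share the NC libraries. Simulated drug groups without effect gave a mean r of 0.502 (SD 0.0167) and at most 0.533, and a covariance of 0.0107 against 0.0334 observed. The simulated counts held no trend on GC content and length between libraries. At day 2 the data held one for both drugs against the same NC library (R squared 0.564 for naloxone and 0.541 for DAMGO). The excess over the simulated values is therefore not a measure of a shared drug effect. With NC libraries of different stages for each drug the median r was 0.203 (-0.08 to 0.571). The highest values, 0.571 and 0.561, came where the naloxone stages held day 8 and the DAMGO stages held day 2. The other splits gave at most 0.267. Against NC these libraries had a like trend on GC content (r across genes 0.617 for naloxone at day 8 and 0.616 for DAMGO at day 2). Without the day 2 libraries, an alternative added after the data had been seen, r was 0.457. Within stages r was 0.511 in undifferentiated cells, 0.939 at day 2, 0.461 at day 4 and 0.420 at day 8.

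No measured member of the gene lists passed for either drug over the 4 stages, also when adjusted over the list alone. With the preset correlation camera put glycolysis and hypoxia genes higher with naloxone (adjusted p = 0.0432) and with DAMGO (0.00258), the 6 sex-linked genes lower with both (0.0223 and 0.00299), and genes of G2 and M phase lower with DAMGO (0.00299). None of these 5 calls was left with an estimated correlation, where the adjusted p = 0.787 for both naloxone lists, and 0.728, 0.728 and 0.506 for those of DAMGO. Every list that passed in any comparison had its median, mean and test in the same direction. Tet1 and Tet2, which oxidise methylated cytosine, passed with neither drug over the 4 stages (naloxone -0.72 ± 0.28 and -0.59 ± 0.28), and over differentiation they stood at 79.5 and 56.4 CPM in undifferentiated cells, 41.2 ± 26.8 and 39.6 ± 28.9 at day 2, where NC lay above both drugs, 103 and 75.6 at day 4 and 19.6 and 14.3 at day 8. Tet3, of the same enzyme family, stood at 200, 172, 168 and 97.9 CPM.

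Whether a drug acts differently on undifferentiated and differentiating cells was tested by an interaction with 4 residual degrees of freedom. It called 0 genes for naloxone (226 at an unadjusted p under 0.05) and 0 for DAMGO (212) in edgeR, while DESeq2 called 2 for naloxone, 1 higher and 1 lower, and 0 for DAMGO, and limma-voom called 0 for both. The smallest p for naloxone belonged to Gfap, with a difference of 2.55 ± 0.50 between states where its undifferentiated levels were 0.691 to 4.03 CPM, and to S100b, a calcium-binding protein of astrocytes (-1.93 ± 0.42), and for DAMGO to the smooth muscle genes Acta2 (-4.79 ± 0.64) and Tagln (-1.91 ± 0.51), all with an adjusted p = 1. In data simulated for this interaction 1.25% of genes changed 1.5-fold, 6.25% of those changed 2-fold and 72.5% of those changed 4-fold were called.

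Drug effects within each stage were tested after the data had been seen, with 1 library for each drug and 1 for NC. The drug terms of a stage fit its 3 libraries exactly, so that the spread, with 4 residual degrees of freedom, comes from the other 3 stages alone and the libraries of the stage tested are assumed to vary like them. The difference between the drug and NC libraries at day 2 is thus left out of the spread at day 2. In the tests of undifferentiated cells, day 4 and day 8 the spread holds it. The counts called at these stages and at day 2 can therefore not be compared with one another. Away from day 2, most counts at an unadjusted p under 0.05 lay below the 657 expected by chance. Those of naloxone against NC and of naloxone against DAMGO at day 8 lay above it. At day 2 most genes called with either drug were lower than in NC. Tet1 stood at 71.7 CPM in NC, 21.3 with naloxone and 30.6 with DAMGO, and Tet2 at 72.8, 20.4 and 25.5. Tet3, of the same family, stood at 184, 159 and 174 CPM and was called with neither drug. Its log2 difference was -0.22 ± 0.14 with naloxone and -0.08 ± 0.14 with DAMGO. The log2 difference of Tet1 with naloxone was -1.75 ± 0.32 (edgeR adjusted p = 0.00264), and -0.98 ± 0.25 (0.0152) with a trend on GC content and length removed, and with DAMGO it was -1.23 ± 0.32 (0.0323) and -0.66 ± 0.25 (0.151). For Tet2 it was -1.84 ± 0.18 (0.000255) and -0.67 ± 0.14 (0.00555) with naloxone, and -1.51 ± 0.18 (0.00393) and -0.62 ± 0.15 (0.0240) with DAMGO. Of 18 genes of DNA methylation and its removal 1 was higher and 3 lower with naloxone, and 2 and 2 with the trend removed (adjusted p = 0.976 with an estimated correlation), and with DAMGO 1 was higher and 2 lower, and 0 and 1 with the trend removed (0.963). In edgeR naloxone called 2176 genes, 206 higher and 1970 lower, and DAMGO called 1319, 53 higher and 1266 lower, while 0 were called in undifferentiated cells, at day 4 and at day 8 (159, 150 and 734 for naloxone and 216, 177 and 176 for DAMGO at an unadjusted p under 0.05). In data simulated for naloxone against NC at day 2, this test called 0% of genes changed 1.5-fold, 15% of those changed 2-fold and 87.5% of those changed 4-fold, so that changes of 2-fold or less at the other stages would mostly not be detected. The simulated spread was that of the additive fit, which holds the day 2 difference, so the share called at day 2 itself may be higher. Without the naloxone library of day 8 edgeR called 3703 with naloxone at day 2, 1096 of them higher, and 2830 with DAMGO, 676 of them higher. DESeq2 called 1329 and 717, and limma-voom 2263 and 1340. Both drugs shared 1246 of the genes called in the same direction, and both comparisons used the same single NC library. In 10 simulations without a drug effect, which share that library in the same way, the highest number was 1 call per drug and 0 shared calls. Independent lists of the observed sizes would share 191 genes, a value that leaves out the shared library, so the excess over either number is not a measure of a shared effect. The log2 difference at day 2 rose with gene GC content (r = 0.611 for naloxone and 0.616 for DAMGO) and fell with transcript length (r = -0.461 and -0.442), across genes, which are not independent replicates. At day 8 the naloxone library had a like trend on GC content (r = 0.617). Naloxone minus DAMGO, which uses no NC library, also rose with GC content, at day 8 (r = 0.682) and less so at day 2 (r = 0.334). With the trend on GC and length removed, naloxone called 766 higher and 880 lower at day 2, and DAMGO 266 higher and 394 lower, and in undifferentiated cells naloxone called 1, the predicted gene Gm14434, at 19.9 CPM against 1.21 in NC, named after its values were seen. Of the genes first called, 857 and 383 were called again in the same direction. With the size factors of DESeq2 in edgeR the split was 634 higher and 1755 lower for naloxone and 204 and 990 for DAMGO. Naloxone against DAMGO called 0 genes at day 2 (473 at an unadjusted p under 0.05).

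**Figure D3:**
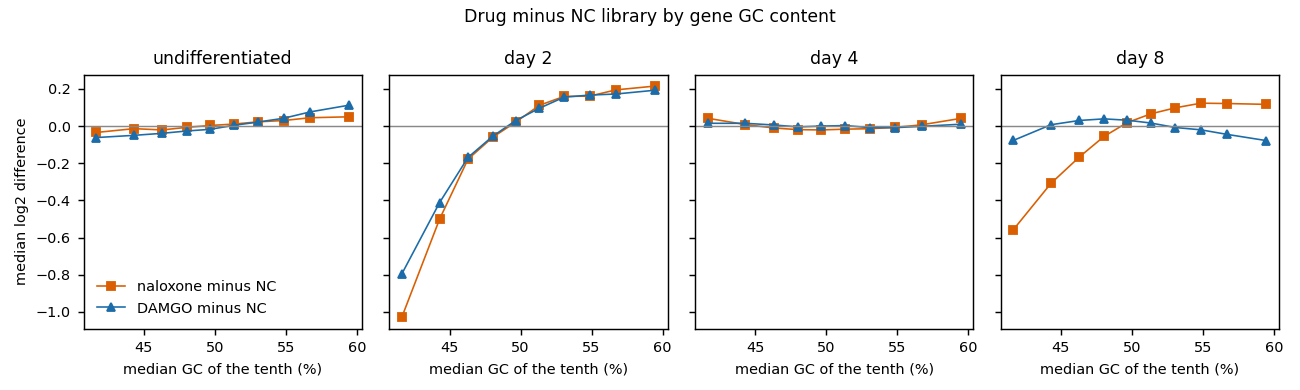
Median log2 difference in CPM between a drug library and the NC library of its stage (y axis) in groups of genes of equal size ranked by GC content (x axis), 1 line per drug in a panel per stage. At day 2 both lines climb with GC content, and at day 8 that of naloxone does (r across genes 0.611, 0.616 and 0.617).

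Of the 10 largest changes at day 2 in each direction, all kept their sign after the trend was removed. These genes were picked for their size in the same libraries, so a kept sign was likely beforehand. It does not speak for the other genes called. Higher with naloxone were Fzd8, a Wnt receptor, at 12.05 CPM against 5.66 in NC (adjusted p = 0.0290, and 0.0315 with the trend removed), Fndc5, Rnd1, Mocs3 (0.0383, and 0.137 with the trend removed), Pet100, a factor of cytochrome oxidase assembly, and Timp4, an inhibitor of metalloproteases, at 83.8 against 46.1 CPM. Lower with naloxone were Hook1, a linker of cargo to microtubules, at 1.27 against 11.9 CPM, with a log2 difference of -3.21 ± 0.43 and of -2.17 with the trend removed, Fam199x (-3.03 ± 0.31 and -1.13), Zfp120 (-2.98 ± 0.32 and -1.71), Dmxl1 (-2.79 ± 0.42 and -0.94) and Bche, a cholinesterase (-2.78 ± 0.25 and -1.64). Ascc3, a helicase, was at 3.04 against 19.1 CPM, and its adjusted p was 0.0978 with the trend removed. Higher with DAMGO were Ptges2, Pim3, a kinase, the tubulin gene Tuba1c at 78.2 against 44.4 CPM, Mob3a at 35.1 against 20.02, and Capn15, a protease (adjusted p = 0.0175, and 0.0695 with the trend removed). Lower with DAMGO were Tom1, an adaptor of endosomes, which had no count with DAMGO against 45.5 CPM in NC and 32.9 with naloxone (at least 84.4-fold lower than NC), Cip2a (-2.84 ± 0.38 and -1.72 with the trend removed), the Y-linked gene Ddx3y (-2.70 ± 0.48 and -1.36, adjusted p = 0.0997 with the trend removed), Hectd2 (-2.51 ± 0.48 and -1.60) and Zfp605 (-2.39 ± 0.34 and -1.91). Fdps, of isoprenoid synthesis, stood at 102 CPM in NC, 172 with naloxone and 161 with DAMGO. Lists with a higher median with naloxone fared differently with the trend removed. The median log2 difference went from 0.28 to 0.04 for ribosomal protein genes and from 0.26 to 0.10 for oxidative phosphorylation genes. It went from 0.32 to 0.28 for unfolded protein response genes and from 0.25 to 0.32 for cholesterol genes. With naloxone 8 of 23 cholesterol genes were higher and none lower, and 9 with the trend removed (adjusted p = 0.842 with an estimated correlation). With DAMGO, against the same NC library, 1 of the 23 was higher and none lower, and 5 with the trend removed (0.828). Of the 6 sex-linked genes 5 were lower with naloxone and 5 with DAMGO, and 1 with either when the trend was removed (0.455 and 0.698).

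The passage 13 and passage 8 libraries ask what further culture changes. Each is 1 library without a replicate check, assumed to vary like the other 12. For some genes named below, undifferentiated NC, also at passage 8, stood nearer to passage 13 than to the passage 8 reference. It stood at 17.5 CPM for Gja1, 24.2 for Ank3, 0.807 for Emp1 and 138.5 for Mapt. For Pdgfra and Gas6 it lay between them, at 25.8 and 41.7 CPM. A difference due to passage can therefore not be told apart from one of the passage 8 reference library. Pdgfra stood at 15.4 CPM at passage 13 and 36.4 at passage 8 (log2 difference -1.24 ± 0.14), Gas6, a ligand of receptor kinases, at 19.5 and 49.8 (-1.35 ± 0.15), and Emp1, a membrane protein named here after its values were seen, at 0 and 5.26. These were the 3 genes called, all lower at passage 13 (adjusted p = 0.0311), with 645 at an unadjusted p under 0.05. The astrocyte junction gene Gja1 (-1.21 ± 0.16), the axon scaffold gene Ank3 (-1.08 ± 0.15) and Gpr17 (-2.69 ± 0.37) had an adjusted p = 0.0520, and Sox10 stood at 0 against 3.13 CPM. Ifi27, an interferon-stimulated gene, stood at 7.24 against 1.15 CPM (adjusted p = 0.0588), and the tau gene Mapt at 124 against 74.2 (0.20). The 7 lists called with the preset correlation were lost with an estimated correlation (smallest adjusted p = 0.246). DESeq2 called 4, limma-voom 2 and limma on log2 TPM 0, and without any 1 of 8 libraries, such as NC at day 8, edgeR called 0, while without NC at day 2 it called 17, without naloxone at day 2 it called 1 and without DAMGO at day 8 it called 6.

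The undifferentiated NC library against the passage 8 NSC library compares cultures of the same passage with no drug named for either. Genes of glycolysis and hypoxia were higher in the NC library. Pdk1, which inhibits pyruvate dehydrogenase, stood at 105 against 14.8 CPM (log2 difference 2.84 ± 0.14), Bnip3, a mitophagy receptor, at 86.7 against 14.8 (2.75 ± 0.20), Ndrg1 at 15.3 against 2.80 (2.58 ± 0.28) and the growth factor gene Vegfa at 125 against 43.8 (1.73 ± 0.23). The glucose transporter genes Slc2a1 and Slc2a3, the hexokinase gene Hk2 and the phosphofructokinase gene Pfkl were also called. In that list 8 of 23 genes rose and none fell (15 adjusted over the list alone), with an adjusted p = 0.0185 with an estimated correlation, and the other 6 lists called with the preset correlation were not. Of the genes outside the lists and named after their values were seen, Slc16a3, a lactate transporter, stood at 16.7 against 0.658 CPM, the clock gene Per1 at 40.1 against 13.98, and Igfbp4 at 46.0 against 139. The comparison called 45 genes, 30 higher and 15 lower, 28 of them at least 2-fold. The passage 8 side is 1 library, and the NC side, in these calls and in the log2 differences, is the undifferentiated NC level fitted by the additive model to the 12 libraries, so that a log2 difference can depart from the ratio of the CPM beside it. Without the NC library of day 2 the comparison called 125 and without that of day 8 it called 18. Without undifferentiated NC, naloxone or DAMGO it called 15, 22 and 17, and without DAMGO at day 4 it called 22.

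**Figure D4:**
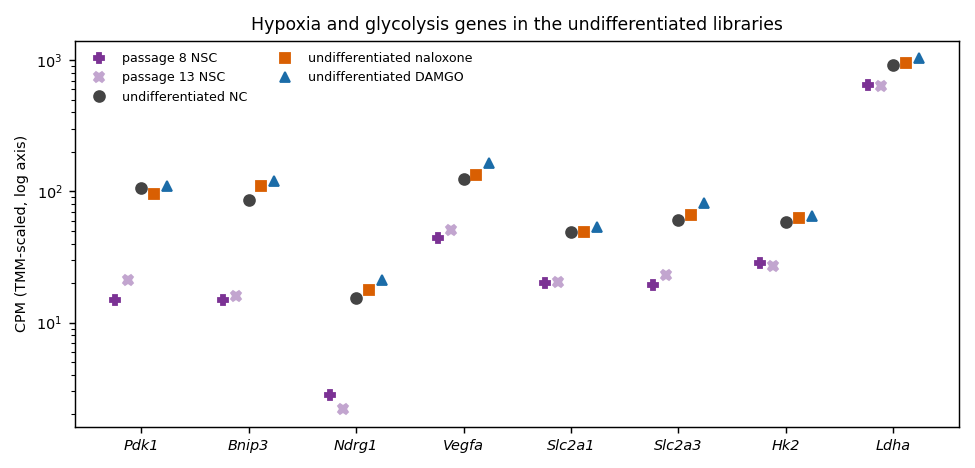
CPM on a log axis of 8 glycolysis and hypoxia genes in the 2 reference libraries and the 3 undifferentiated libraries, where each point is 1 library. Pdk1 stands at 14.8 and 21.2 CPM in the references at passage 8 and passage 13 and at 105 in undifferentiated NC.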

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

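All tests of explanations in this part, and the fits of drug effects within a stage, were chosen after the results they bear on had been seen. The effect of naloxone at day 2 differed from its mean effect at the other stages in 1441 genes (59 higher and 1382 lower), and that of DAMGO in 725 (20 higher and 705 lower), by edgeR's test of the difference with 4 residual degrees of freedom. With the GC and length trend removed within stages these counts were 829 (327 higher and 502 lower) and 195 (65 higher and 130 lower). The effect of DAMGO at day 8 differed from the other stages in 2 genes, the predicted genes Gm10800 and Gm26870, named after their values were seen. At day 8 Gm10800 stood at 16.5 CPM in NC, 49.2 with naloxone and 2.42 with DAMGO, and at day 2 at 0.145, 0.507 and 27.0. Gm26870 stood at 17.8, 51.3 and 3.46 CPM at day 8, and at 0.290, 0.380 and 20.5 at day 2. DAMGO against NC at day 8 itself had an adjusted p = 1 for both genes, and the difference between stages rests also on the DAMGO library of day 2.

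At day 2 the drug libraries lay below the NC library in most genes called. Whether a trend on GC content and length between libraries gives that direction stays open. Of the naloxone calls 90.5% were lower as deposited and 53.46% with the trend removed, but the removal centres the differences at every GC content and length, so that a more even split follows from it whatever the source. In simulated data with the measured trend and no changed gene, naloxone at day 2 gave 432 calls, 97.2% of them lower, and 2 after the removal. Such a trend alone can thus give calls in this direction. The simulated spread was that of the additive fit, which already holds the day 2 difference, so the number cannot be set against that observed. The removal there used the same kind of fit as the simulated trend, so the 2 left say nothing about a bias of another shape. The trend as fitted is not the whole of the calls, because 857 of the 2176 naloxone calls were called again in the same direction after its removal. The fit is smooth and was made on the more highly expressed genes. A bias between libraries that it leaves in place would also be called again, so a library origin of these calls stays open. Drug cultures further along towards day 8 stay open, as the 100 genes with the largest rise from day 4 to day 8 had a median log2 difference of 0.1526 between naloxone and NC at day 2, with 68 of them higher and quartiles of -0.04 and 0.35. A single NC library that stands apart also cannot be told apart from an effect of both drugs, since both are set against that library and no other NC library of day 2 gives a spread. The correlations across genes do not decide it. At day 2 NC had r = 0.9534 with NC at day 4 and 0.8766 with undifferentiated NC. The naloxone library had lower values with its own neighbours (0.905 and 0.8279), and so had the DAMGO library (0.920 and 0.8401). With day 8 the order was reversed, in correlations taken over a set that includes the reference libraries. There r was 0.8743 for NC, 0.8974 for naloxone and 0.896 for DAMGO, each with day 8 of its own treatment. An effect of the drugs themselves stays open as well, with 0 genes called between naloxone and DAMGO at day 2 by edgeR (473 at an unadjusted p under 0.05).

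Genes of glycolysis and hypoxia were higher in the undifferentiated libraries of the drug experiment than in the reference libraries. Of 24 genes, 19 stood above both references in all 3 undifferentiated libraries and 0 below both, where chance gives 10% each way. The median log2 difference was 0.60, at percentile 100 of 10000 random lists matched on expression. The list had been singled out from these same libraries, and random lists do not keep a correlation among its genes. Neither the 10% nor the percentile is therefore a measure of chance for this list. A trend on GC content and length is argued against, since the median between undifferentiated NC and passage 8 NSC was 0.58 before and 0.6078 after its removal. A separate culture or library batch stays open with the 19 genes, because the labels give no batch and the references have no drug arm beside them, and no biological explanation was tested.

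No gene passed for either drug over the 4 stages. A candidate explanation is mu and kappa opioid receptor RNA below detection, which may account for this, since the larger of the total counts of Oprm1 and Oprk1 over 14 libraries was 0. That count was known beforehand, so this test could not have come out otherwise. Receptor protein was not measured, and other receptors for either drug stay open. The spread of the additive model holds any drug effect that differs between stages, such as a difference at day 2. No gene past the threshold over the 4 stages therefore does not show that the drugs had no effect. With the treatment names permuted within stages, a real count of 0 is reached in 50 of 50 draws by construction, so the draws say nothing about chance. The highest of the other draws was 1 for naloxone, 0 for DAMGO and 0 for naloxone against DAMGO.

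For the stages, the 6 libraries of a pair allow 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes each time, at 9156 for day 2, 8192 for day 4, 10532 for day 8 and 7727 for day 8 against day 2, where the highest other split gave 0.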

How the results depend on the processing

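The removal of a trend on GC content and length, the fits within day 2, the lists of the passage comparisons, and the fits and the correlation without the day 2 libraries were added after the data had been seen, and the other alternatives were planned. The cause of a change was not tested unless stated. With a minimum change of 2-fold, which keeps fewer genes by construction, the counts were 4431 at day 2, 3728 at day 4, 6241 at day 8, 3116 for day 8 against day 2, 28 for undifferentiated NC against passage 8 NSC, and 1267 for naloxone and 769 for DAMGO within day 2. With the trend removed across libraries passage 13 gave 15, NC against passage 8 NSC gave 179 and naloxone by state gave 1, and within stages naloxone by state gave 1 and DAMGO at day 2 gave 660. DESeq2 gave 2 for naloxone by state, 1329 for naloxone at day 2 and 717 for DAMGO at day 2. Passage 13 gave 7 with no filter on low counts and 0 with limma on log2 TPM. With an estimated correlation 8 lists passed at day 4, 3 at day 8, 0 for naloxone, 0 for DAMGO, 0 for passage 13 and 1 for NC against passage 8 NSC, and 9 at day 2. The correlation between the drugs was 0.2031 with split NC libraries, 0.457 without the day 2 libraries and 0.7573 with the trend removed. With the trend removed across libraries the log2 change of Xist was 0.0603 at day 2, that of Uty 0.1508 at day 2 and 0.2319 at day 8, and that of Ogfr -0.092 at day 8, each the reverse of the value reported. With each library left out, day 2 gave 8241 to 9577, day 4 7318 to 9128, day 8 10010 to 11003 and day 8 against day 2 6552 to 7713. Naloxone at day 2 gave 1869 to 3703 and DAMGO at day 2 955 to 2830, both highest without naloxone at day 8. DAMGO against NC and naloxone against DAMGO gave 0 to 2, with 2 without DAMGO at day 8. Passage 13 gave 0 to 17, with 0 without any undifferentiated library, DAMGO at day 2, any day 4 library or NC at day 8, 1 without naloxone at day 2, 6 without DAMGO at day 8 and 17 without NC at day 2. NC against passage 8 NSC gave 15 to 125, with 15, 22 and 17 without undifferentiated NC, naloxone and DAMGO, 22 without DAMGO at day 4, 18 without NC at day 8 and 125 without NC at day 2. The interactions have no value without undifferentiated NC, and each has none without the undifferentiated library of its drug. Of the values of named genes under all alternatives 2535 at day 2, 2672 at day 4 and 3038 at day 8 kept their direction and side of the threshold, while 61, 34 and 20 lost the threshold. For passage 13 25 values gained it and 21 lost it, and for NC against passage 8 NSC 39 lost it. The drug fits hold stage as a block, and no pairing by replicate number was possible because the labels give none. Depth limits genes below 0.354 to 0.693 CPM in a library.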

Other observations

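The tests of explanations in this part were chosen after the values had been seen. Markers of other cell types moved in both directions over differentiation, and no list of them passed with camera. Of 16 fibroblast, pericyte and smooth muscle genes 6 were measured, with 3, 2 and 4 higher and 1, 1 and 2 lower at days 2, 4 and 8 (adjusted p = 0.457 at day 8 with an estimated correlation). Pdgfrb, a receptor of pericytes, rose from 0.365 ± 0.347 CPM to 102 ± 0.352 at day 4 and 97.8 ± 10.1 at day 8 (SD, n = 3), and Myl9, a myosin light chain of smooth muscle, from 1.25 ± 0.663 to 141 ± 11.2 at day 8. Of 6 ependymal genes 1, 1 and 4 were higher and 2, 1 and 2 lower (0.457). Foxj1, a master regulator of motile cilia, rose from 5.62 ± 0.686 CPM to 46.2 ± 3.57 at day 4 and 226 ± 26.1 at day 8, while Hydin, a protein of motile cilia, fell from 13.0 ± 1.79 to 0.406 ± 0.435. Of 6 neural crest and Schwann cell genes 2, 3 and 3 were higher and 3, 2 and 2 lower (0.877). Of 4 endothelial genes 0, 1 and 2 were higher and 1 lower each time (0.877), and Kdr, a receptor for vascular growth factor, rose from 2.0 ± 0.368 to 20.6 ± 3.83 CPM at day 8. The list of 17 microglia genes had fewer than 3 measured members and was not tested. Of 3 pluripotency genes 1 was higher and 2 lower at each day (0.877), and Esrrb, a nuclear receptor, fell from 9.72 ± 1.85 to 0.585 ± 0.311 CPM at day 8.

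Matrix genes went both ways at the earlier days, with 7 of 14 higher and 6 lower at day 2, and 6 higher and 7 lower at day 4, where the sign of the median turned with TPM scaling. Thbs1, a matrix glycoprotein, rose from 2.60 ± 1.28 CPM to 45.1 ± 4.82 at day 4 and 246 ± 63.1 at day 8, and Lamb1, a laminin chain, fell from 48.1 ± 5.54 to 4.38 ± 0.556 at day 8. Of 16 imprinted genes 6 were higher and 9 lower at day 2, and 4 higher and 4 lower at day 4, with Mest, a hydrolase gene, going from 480 ± 16.5 to 89.4 ± 5.84 CPM and Nnat, a neuronal membrane protein, from 247 ± 13.1 to 1043 ± 58.1 at day 4. Of 22 unfolded protein response genes 4 were higher at days 2 and 4 and 10 and 14 lower, with Asns, which makes asparagine, going from 104 ± 8.13 to 23.8 ± 2.63 CPM at day 4.

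Xist, the RNA of the inactive X chromosome, stood at 259 to 2189 CPM and the Y-linked genes Ddx3y at 1.80 to 39.3, Kdm5d at 10.8 to 44.2, Eif2s3y at 4.96 to 50.4 and Uty at 2.36 to 21.5 CPM in the 14 libraries. Cells of both sexes in every culture may give this, but the lowest value of either Xist or Ddx3y in any library was 1.798 CPM, between the bounds set for and against it, so that it stays open. Of the 6 sex-linked genes 5 were lower at day 2, 0 at day 4 and 6 at day 8 (adjusted p = 0.760, 0.967 and 0.856 with an estimated correlation). With the GC and length trend removed across libraries, an alternative added after the data had been seen, the log2 change turned its sign and lost its call for Xist at day 2 (0.0603, edgeR adjusted p = 0.575) and for Uty at day 2 (0.1508, 0.414) and day 8 (0.2319, 0.252).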
